A study of Drosophila melanogaster with 12 samples.

How the data were processed

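RNA was measured by sequencing of poly(T)-captured transcripts in 12 libraries, 3 biological replicates of each of 4 genotypes. Per the labels, embryos were sorted by hand, to leave out those not developing and to keep equal proportions of cellularizing and gastrulating embryos. Several collections were pooled per replicate. The collection window differed with how many eggs a genotype laid, either 1 h with 1.5 to 2 h of ageing or 2.5 to 3 h taken directly, at 28 C, and the labels do not say which genotype had which. The window and the genotype may therefore be confounded. Libraries were made from 200 ng of total RNA.

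The authors deposited raw read counts per gene, the unit tested here, and the deposited normalized values are a signal equal to those counts times 1 constant per library (largest relative deviation 9.84e-15). The authors also deposited DESeq2 tables with a log2 fold change, a p value and an adjusted p value per gene for each genotype against control. The submitters' processing notes name Trimmomatic, Bowtie2 2.2.4, HISAT2 2.1.0, featureCounts 1.5.2 and DESeq2, with no role or order. The genome build and the strand used in counting are not stated, so no coordinates are given and reads of overlapping genes may be assigned to either. How reads of near-identical copies were counted, as in the Bearded family, the Hsp70 genes and mitochondrial ribosomal RNA, is not stated either. The RefSeq annotation of Drosophila melanogaster served for gene names and for the order of genes along chromosomes.

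Libraries held 61757756 to 91949037 reads in genes, and 11001 to 11731 of 17868 genes had a read. A count of 3 corresponds to 0.0326 to 0.0486 CPM per library by unscaled totals. The floor used for mthl8, which had no reads in SOD2i, was 0.0468 CPM, 3 counts in the SOD2i library of smallest TMM-scaled size. It covers counting error only, since reads without molecular identifiers are not independent molecules. Mitochondrial ribosomal RNA took 4.27% to 9.28% of counts and all mitochondrially encoded genes 5.94% to 12.1%. Replicates of a genotype correlated at r = 0.983 to 0.994 across genes in log2 CPM. The common biological coefficient of variation was 0.1755.

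Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, scaled by TMM and fitted with a quasi-likelihood model of all 12 libraries with 1 mean per genotype, which left 9863 genes. Each single genotype and the double genotype were compared with control, the double genotype with each single one, and the interaction was tested as a contrast. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. The 34 gene lists were written before the data were examined, as were the comparisons and tests in this section except where it says otherwise. The 33 lists with at least 4 tested genes were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. The list of transgene marker genes had 2 tested genes and was not tested. With an estimated correlation, 0 of the 38 list calls hold, and their lowest adjusted p is 0.0886, so a list call here rests on the preset value. List means per library are averages of log2 CPM. Maternal and stage indices were compared by exact two-sided permutation tests, and relations among libraries by permuting within genotypes. The maternal index and its use as a covariate were chosen after the data were seen.

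Named genes were chosen by a rule. Sod2 and Drp1 came first, then up to 10 genes per direction with the largest log2 fold change among called genes that changed at least 2-fold, had a mean of at least 5 CPM and showed no overlap between the libraries compared (not required for the interaction). Symbols that are only a number, such as a CG, CR or lncRNA number, were left out. The gene Dmel_CG8799 has a symbol, made from the number of a lethal allele on chromosome 2, and is given by its identifier instead. Of each list discussed, up to 4 members with the smallest adjusted p were eligible. In the interaction, each gene is also given by its CPM where that helps to read the value. Genes named because a count was 5 or fewer were chosen after their values were seen.

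The alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, no filter or a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma with voom, a fit of only the groups compared, a 2-fold threshold, replicate number as a block, leaving out each library, fry and an estimated correlation for lists, and 2 alternatives on maternal transcripts added later. Where leaving out a library left 2 in a genotype, the fit pooled the spread over all genotypes. The DESeq2 fit run here on all libraries gave no adjusted p for DIP-beta, whereas the authors' deposited tables give one for Drp1SG and none for SOD2i.

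The procedure was tested on simulated data with known changes. In Drp1SG against control it recovered 62.1% of genes changed 2-fold, with 7 false calls among 9713 genes, and for the interaction 46.9% with 4 false calls among 9695 genes. Smaller changes were recovered less often, so a gene not called may still differ. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The authors' lists of enriched terms were not used, since their background is not stated.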

Results

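The series compared the transcriptomes of Drosophila melanogaster embryos of 4 genotypes, each with 3 biological replicates: Control, Drp1SG, SOD2i and the combination Drp1SG;SOD2i, from here on the double genotype. Drp1 encodes the dynamin-related GTPase that divides mitochondria, and Sod2 encodes the manganese superoxide dismutase of the mitochondrial matrix. The labels do not say what the letters SG stand for, and SOD2i is read here as RNA interference against Sod2. Each replicate was a pool of sorted cellularizing and gastrulating embryos. The question named by the series is how mitochondrial fusion and fission affect gene expression at these stages. Expression levels are library-size-scaled counts (CPM), given as means ± SD over 3 replicates, log2 fold changes carry ± their standard error, and adjusted p values come from edgeR over 9863 tested genes unless another test is named. In a principal component analysis of the 12 libraries, the first component held 27.8% of the variance and the second held 24.9%.

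Sod2 (Dmel_CG8905) was measured at 50.8 ± 0.691 CPM in control and 49.5 ± 3.58 CPM in Drp1SG, a difference that was not called (log2 fold change -0.04, adjusted p = 0.896). It stood at 1.82 ± 0.486 CPM in SOD2i, 3.59% of control, a log2 fold change of -4.80 ± 0.19 (adjusted p = 2.79e-08). In the double genotype it stood at 3.04 ± 0.513 CPM, 5.99% of control (log2 fold change -4.06 ± 0.18, adjusted p = 1.89e-07). Sod2 was therefore higher in the double genotype than in SOD2i, by a log2 fold change of 0.74 ± 0.17 (adjusted p = 0.0126). Drp1 (Dmel_CG3210) rose from 36 ± 2.41 CPM in control to 84.0 ± 17.5 CPM in Drp1SG, a log2 fold change of 1.22 ± 0.14 (adjusted p = 1.44e-04). In SOD2i it fell to 22.1 ± 3.02 CPM, 61.3% of control (log2 fold change -0.71 ± 0.14, adjusted p = 0.00335). In the double genotype Drp1 was at 43.6 ± 0.645 CPM, with every library (42.9 to 44.2 CPM) above every control library (34.2 to 38.8 CPM). The difference from control was not called by edgeR (log2 fold change 0.28 ± 0.14, adjusted p = 0.248), and had an adjusted p of 0.0378 in the authors' deposited table. The gain in Drp1 was 47.95 CPM from control to Drp1SG and 21.6 CPM from SOD2i to the double genotype. On the log2 scale no difference between these 2 gains was called (interaction -0.24, adjusted p = 0.467).

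**Figure D1:**
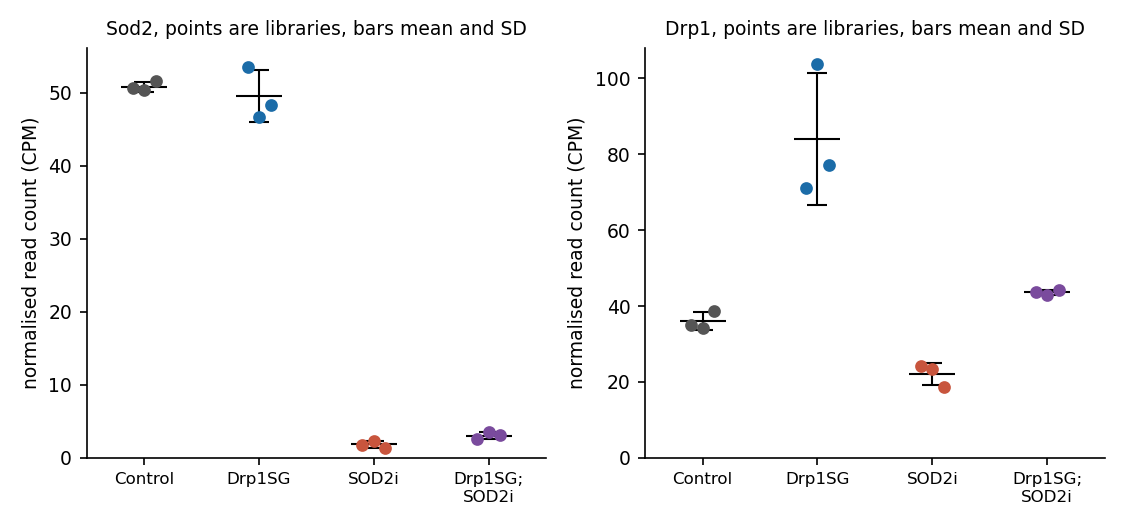
CPM of Sod2 and Drp1 in each of the 12 libraries, with the mean and SD of each genotype. Sod2 averaged 50.8 CPM in control, 1.82 CPM in SOD2i and 3.04 CPM in the double genotype, and Drp1 was highest in Drp1SG at 84.0 CPM.

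Transcripts loaded into the egg and cleared in the early embryo were followed with a maternal index, the mean log2 CPM of 32 unstable maternal transcripts. It averaged 5.39 ± 0.50 in control, 6.39 ± 0.22 in Drp1SG, 5.55 ± 0.67 in SOD2i and 5.83 ± 0.18 in the double genotype. Every Drp1SG library lay above every control library, a difference of 1.00 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The difference from control was 0.44 for the double genotype (exact p = 0.1) and 0.16 for SOD2i (exact p = 0.6). Control replicate 3 (4.81) and SOD2i replicate 2 (4.84) had the lowest index. The other control libraries stood at 5.69 and 5.66 and the other SOD2i libraries at 6.15 and 5.67. The double genotype stood at 6.04, 5.71 and 5.73, so much of its difference rests on Control replicate 3. The sign of the SOD2i difference also depends on that control library. A stage index was the mean log2 CPM of segment polarity and Hox genes minus that of the early zygotic wave. It was -1.93 ± 0.57 in control, and differed from it by 0.49 in Drp1SG, -0.45 in SOD2i and -0.32 in the double genotype (exact p = 0.3, 0.4 and 0.6). The size of these differences leans on Control replicate 3, at -1.28 against -2.35 and -2.17 in replicates 1 and 2. The double genotype's libraries, at -2.33, -2.43 and -1.99, spread around the latter values, so its difference rests on that control library.

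List means also followed the maternal index among replicates of 1 genotype. Taking each of the 12 libraries as its deviation from its genotype mean, glycolysis gave Pearson r = 0.96 and Spearman rho = 0.91 (permutation p = 0.007 and 0.0075). The citrate cycle gave r = 0.98 and rho = 0.97 (permutation p = 0.007 for each), and the mitochondrial stress response r = 0.92 and rho = 0.92 (permutation p = 0.0068 and 0.0054). For each of these, the Benjamini-Hochberg adjusted p of r over 33 lists was 0.033. Without the 2 libraries whose index deviation lay farthest from the median, r was 0.90, 0.95 and 0.84. Those 2 libraries still entered the genotype means from which deviations were taken, so their influence was not fully removed. The early zygotic wave gave r = 0.72 and rho = 0.65 (permutation p = 0.0522 and 0.0826, adjusted p = 0.123), and r = 0.45 without those 2 libraries, so that relation rests on them.

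**Figure D2:**
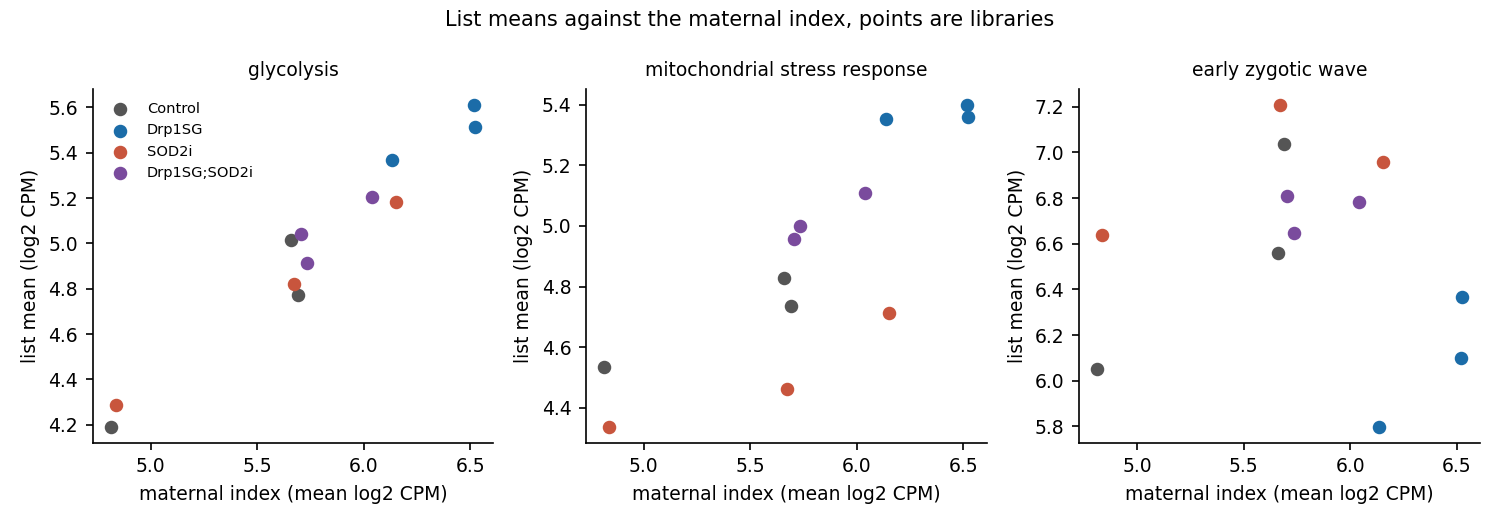
Mean log2 CPM of the glycolysis, mitochondrial stress response and early zygotic wave lists against the maternal index (log2 CPM) of the same library, 1 point per library, coloured by genotype. The mean maternal index was 6.39 in Drp1SG and 5.39 in control, and SOD2i replicate 1 (6.15) lay among the Drp1SG libraries.

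Drp1SG against control asks which transcripts differ in the Drp1SG genotype, whose line background and collection window may differ from control as well. Transcripts of daw, a ligand of the activin branch of TGF-beta signalling, rose from 0.806 ± 0.314 to 16.4 ± 6.06 CPM, a log2 fold change of 4.34 ± 0.35 (adjusted p = 9.45e-06). Drep1, a relative of the inhibitor of the caspase-activated DNase, rose from 8.31 ± 1.51 to 131 ± 22.5 CPM (log2 fold change 3.98 ± 0.17, adjusted p = 2.22e-07). Log2 fold changes were 3.72 for Arc1, a capsid-forming relative of retrotransposon Gag proteins, 3.10 for pst and 2.63 for the ABC transporter gene Dmel_CG8799. The egg transcripts dhd, a germline thioredoxin, and exu, which localises bicoid mRNA, rose by 2.73 ± 0.47 and 2.69 ± 0.40. Cyp6a19, a cytochrome P450, and GstD1, a glutathione transferase, rose by 4.22 and 2.62, and by 5.03 and 3.40 without Control replicate 2. DIP-beta, a neuronal cell surface protein, was at 12.0 ± 2.22 CPM against 0.465 ± 0.164 CPM (log2 fold change 4.69 ± 1.25, adjusted p = 0.0229). The DIP-beta call was lost without any 1 control library or without Drp1SG replicate 3, with an adjusted p of up to 0.0815. In the authors' deposited table it had an adjusted p of 2.81e-68. Adding the maternal index as a covariate lowered the log2 fold changes of dhd to 1.64 and exu to 1.57, both still called. They fell to 2.08 for Cyp6a19 and 1.19 for GstD1, no longer called (adjusted p = 0.1 and 0.12). DIP-beta kept most of its rise, at 3.79 ± 1.96, and was not called (adjusted p = 0.192) because of its wide standard error. The fit pools spread over all genotypes, and DIP-beta was very uneven among the SOD2i libraries.

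By the naming rule, which covers genes with a name and a mean of at least 5 CPM, the first fall in Drp1SG was kek1, a transmembrane inhibitor of the EGF receptor, from 48.4 ± 8.29 to 1.22 ± 0.454 CPM (log2 fold change -5.30 ± 0.31, adjusted p = 1.19e-06). TkR86C, a tachykinin-type neuropeptide receptor, fell from 24.4 ± 0.540 to 1.67 ± 0.120 CPM (log2 fold change -3.87 ± 0.19, adjusted p = 3.74e-07). Sema2b, a secreted semaphorin, fell by 2.85 on the log2 scale, the metalloprotease gene Kul by 2.23, the sodium channel para by 1.84 and Mur2B by 1.75. Log2 fold changes were -1.42 for both nAChRalpha3 and Con, -1.33 for the small RNA methyltransferase gene Hen1 and -1.18 for miple1. In total 1830 genes were called, 959 higher and 871 lower, of which 742 changed at least 2-fold. The majority turned with upper-quartile scaling (760 higher and 1010 lower), a filter of 1 CPM (824 and 881) and the maternal index as a covariate (923 and 998). Without Drp1SG replicate 2 the count was 1112. With the maternal index as a covariate it was 1921, and 933 genes were called in both fits.

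**Figure D3:**
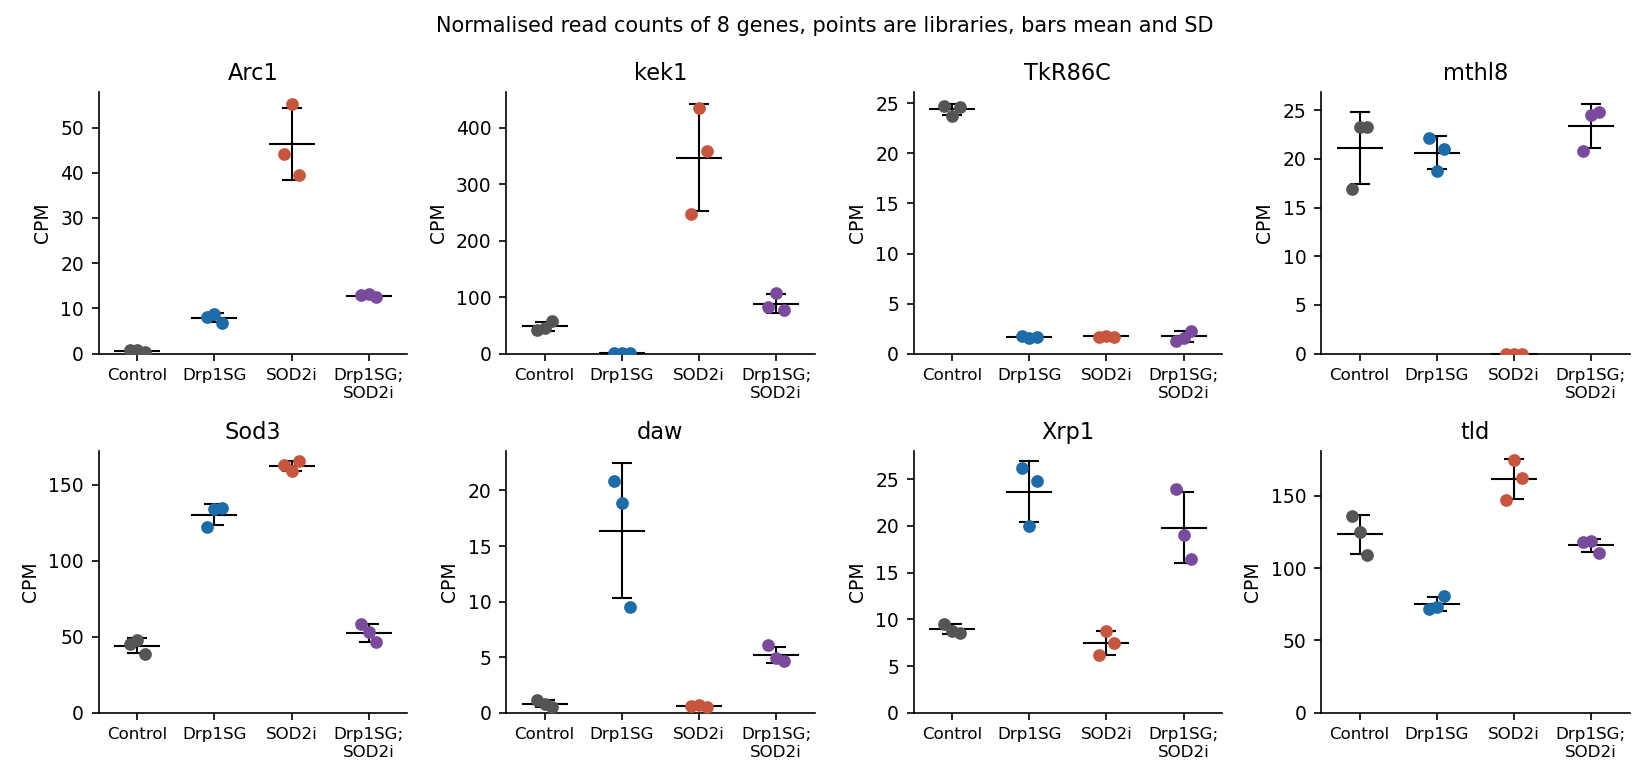
CPM per library for Arc1, kek1, TkR86C, mthl8, Sod3, daw, Xrp1 and tld, with the mean and SD of the 3 libraries of each genotype and a separate linear axis per gene. kek1 averaged 1.22 CPM in Drp1SG and 347 CPM in SOD2i, and mthl8 had no read in any SOD2i library.

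Of 15 tested genes of the mitochondrial stress response, a list of mitochondrial chaperones and ATF4 pathway genes, 8 were higher in Drp1SG and 0 lower (10 higher adjusted over the list alone). The list mean rose by 0.67 ± 0.10 log2 units (camera adjusted p = 2.04e-04, adjusted p = 0.0886 with an estimated correlation). crc, the fly ATF4, rose from 155 to 331 CPM. Xrp1, a stress-induced bZIP factor, rose from 8.94 to 23.7 CPM, the insulin-binding ImpL2 from 59.1 to 103 CPM and Shmt from 5.91 to 12.7 CPM. Of 14 glycolytic genes, 6 were higher and 0 lower (9 higher and 1 lower adjusted over the list alone). Among them, Tpi rose from 2.66 to 14.4 CPM and Pfk from 34.3 to 59.6 CPM. Gapdh2 rose by a log2 fold change of 2.36, and by 2.98 without Control replicate 2. The glycolysis mean rose by 0.84 ± 0.26 (camera adjusted p = 0.00126, adjusted p = 0.505 with an estimated correlation). Of 17 citrate cycle genes, 5 were higher and 0 lower (5 and 0 adjusted over the list alone), among them kdn, 227 to 303 CPM, and Mdh2, 5.28 to 19.3 CPM. The citrate cycle list had a camera adjusted p of 0.00911 (adjusted p = 0.559 with an estimated correlation), and 0.0745 without Control replicate 3. With the maternal index as a covariate, the mean differences became 0.40 ± 0.06 for the mitochondrial stress response, 0.13 ± 0.11 for glycolysis and 0.01 ± 0.05 for the citrate cycle.

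Of the 32 unstable maternal transcripts, 12 were higher in Drp1SG and 0 lower (14 higher adjusted over the list alone), with a camera adjusted p of 1.32e-07 (adjusted p = 0.505 with an estimated correlation). Hsp83 rose from 381 to 867 CPM and fs(1)K10 from 81.3 to 119 CPM. Of 17 germline genes, 7 of which are also in the maternal list, 6 were higher and 0 lower (7 higher adjusted over the list alone). Among these, pgc rose from 13.6 to 30.6 CPM and ovo from 46.5 to 91.4 CPM (camera adjusted p = 0.00126, adjusted p = 0.505 with an estimated correlation). Of 9 early zygotic wave genes, tld, Z600 and term were lower (5 lower adjusted over the list alone). tld, a protease that releases Dpp, fell from 123 to 75.2 CPM, the mitosis inhibitor Z600 from 186 to 97.1 CPM and term from 318 to 208 CPM. The early zygotic list had a camera adjusted p of 0.00745 (adjusted p = 0.505 with an estimated correlation), and 0.0641 without Control replicate 1. Its list mean was 7.04, 6.56 and 6.05 in the control replicates and 5.80, 6.10 and 6.37 in those of Drp1SG. These ranges overlap, and much of the size of the fall rests on Control replicate 1. The pair-rule list was lower (4 of 10 genes, 5 adjusted over the list alone, camera adjusted p = 0.00911, adjusted p = 0.505 with an estimated correlation), with slp1 falling from 163 to 119 CPM. The dorsal ectoderm list was lower as well, with 2 of 16 genes called, tld and pnr (4 adjusted over the list alone, camera adjusted p = 0.00788, adjusted p = 0.505 with an estimated correlation). The pnr call was lost without Control replicates 1 or 3 or Drp1SG replicates 2 or 3 (adjusted p of up to 0.142). The early zygotic wave was still called with the maternal index as a covariate, its mean difference going from -0.46 ± 0.26 to -0.99 ± 0.27 (camera adjusted p = 0.00147). Under that covariate calls ended for germline genes, from 0.74 ± 0.23 to 0.11 ± 0.07 (camera adjusted p = 0.616), the pair-rule list, from -0.28 ± 0.07 to -0.26 ± 0.11 (0.386), and the dorsal ectoderm list, from -0.27 ± 0.05 to -0.17 ± 0.06 (0.616).

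Mitochondrially encoded transcripts were lower in Drp1SG, by a mean log2 difference of -0.53 ± 0.19 over 15 genes (camera adjusted p = 2.22e-04, adjusted p = 0.505 with an estimated correlation). Of these, 5 were lower and 0 higher (8 lower adjusted over the list alone). With the maternal index as a covariate the difference was -0.23 ± 0.24 and the list was not called (camera adjusted p = 0.213). The large ribosomal RNA, lrRNA, fell from 78048 to 44444 CPM, a log2 fold change of -0.81 ± 0.15 (adjusted p = 0.00397). Poly(T) capture samples the mitochondrial ribosomal RNAs through their tails, so these values are levels of captured RNA. Nuclear genes for oxidative phosphorylation were not called as a list (camera adjusted p = 0.515), with 4 of 68 higher and 3 lower. Under the covariate they were called higher, the mean difference going from 0.04 ± 0.05 to 0.14 ± 0.05 (camera adjusted p = 0.0109). That rise rests on extending a slope, as the index did not overlap between control and Drp1SG. blw, the alpha subunit of ATP synthase, rose from 384 to 506 CPM and ND-B16.6 of complex I fell from 80.1 to 61.5 CPM. Of 43 antioxidant and redox genes, 10 were higher and 5 lower (12 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0543). Sod3, the extracellular superoxide dismutase, rose from 44.0 to 130 CPM (log2 fold change 1.56 ± 0.10, adjusted p = 1.89e-06).

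SOD2i against control asks which transcripts differ in the SOD2i genotype, with the same limits of line background and collection window. Arc1 rose from 0.598 ± 0.143 to 46.3 ± 7.98 CPM, a log2 fold change of 6.27 ± 0.21 (adjusted p = 1.01e-08). Dmel_CG8799 rose by 4.47, pst by 4.01, Drep1 by 3.56, the glycosyltransferase gene Ugt36E1 by 3.22 and tbc by 2.96. DNaseII, the acid nuclease of lysosomes, rose from 18.5 ± 2.40 to 143 ± 28.0 CPM (log2 fold change 2.95 ± 0.15, adjusted p = 1.32e-07), and Pde8, a cyclic nucleotide phosphodiesterase, rose by 2.74. kek1, which fell in Drp1SG, rose here from 48.4 ± 8.29 to 347 ± 94.1 CPM (log2 fold change 2.84 ± 0.26, adjusted p = 1.71e-05). DIP-beta had a log2 fold change of 5.17 ± 1.27, which rests on SOD2i replicate 3 at 47.7 CPM, since the other libraries held 1.17 and 1.23 CPM. Without that library it was 1.38, and without Control replicate 2 its adjusted p was 0.0507.

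mthl8, a receptor of the methuselah family, was at 21.1 ± 3.68 CPM in control and had no read in any SOD2i library, at least 452-fold lower by a floor of 3 counts per library. TkR86C fell by 3.84 on the log2 scale, as far as in Drp1SG. Kul fell by 2.44, the ubiquitin hydrolase gene Uch by 2.17, the actin-binding cib by 1.93 and para by 1.91. Uch went from 45.6 ± 4.40 to 10.1 ± 3.27 CPM and cib from 108 ± 9.33 to 28.3 ± 12.1 CPM. Syngr fell by 1.87 and BobA, a Bearded family gene with near-identical copies, by 1.77. Calx, a sodium-calcium exchanger, fell by 1.88, and by 3.14 without SOD2i replicate 1. The Calx call was lost without any 1 control library or SOD2i replicate 3 (adjusted p of up to 0.139). In total 2286 genes were called, 1019 higher and 1267 lower, of which 885 changed at least 2-fold. With upper-quartile scaling the split was 632 higher and 1435 lower, and a fit of only the control and SOD2i libraries called 1263 genes.

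The adhesion and polarity list was higher in SOD2i. Of 22 genes, 8 were higher and 0 lower (9 higher and 1 lower adjusted over the list alone), with a mean log2 difference of 0.25 ± 0.04 (camera adjusted p = 0.00709, adjusted p = 0.915 with an estimated correlation). baz, the Par3 of flies, rose from 235 to 358 CPM, scrib from 663 to 815 CPM and Fas3 from 3.07 to 10.9 CPM. Of 10 gap genes, btd, ems, oc and kni were higher and 0 lower (4 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.915 with an estimated correlation). btd rose from 30.9 to 44.4 CPM and ems from 26.6 to 35.7 CPM. The oc call was lost without SOD2i replicate 2, and the kni call without that library or any 1 control library (adjusted p of up to 0.0538 and 0.112). The mitochondrial stress response had 6 genes lower and 0 higher (6 and 0 adjusted over the list alone) and was not called (camera adjusted p = 0.249, mean log2 difference -0.20 ± 0.10). Among them the mitochondrial chaperones Hsc70-5, 99.6 to 73.0 CPM, and Trap1, 38.7 to 29.6 CPM, fell. The antioxidant list was split, with 7 of 43 higher and 8 lower (8 and 10 adjusted over the list alone, camera adjusted p = 0.751). Sod3 rose from 44.0 to 162 CPM and GstD9 from 11.0 to 30.0 CPM, whereas GstS1 fell from 240 to 148 CPM. Actomyosin regulators were not called as a list (camera adjusted p = 0.249), with 6 of 36 higher and 1 lower. Among these, mthl1, the receptor for Fog in the mesoderm, rose from 108 to 139 CPM and capt from 235 to 312 CPM. None of the 15 mitochondrially encoded genes was called by edgeR in SOD2i (0 also adjusted over the list alone, camera adjusted p = 0.497).

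**Figure D4:**
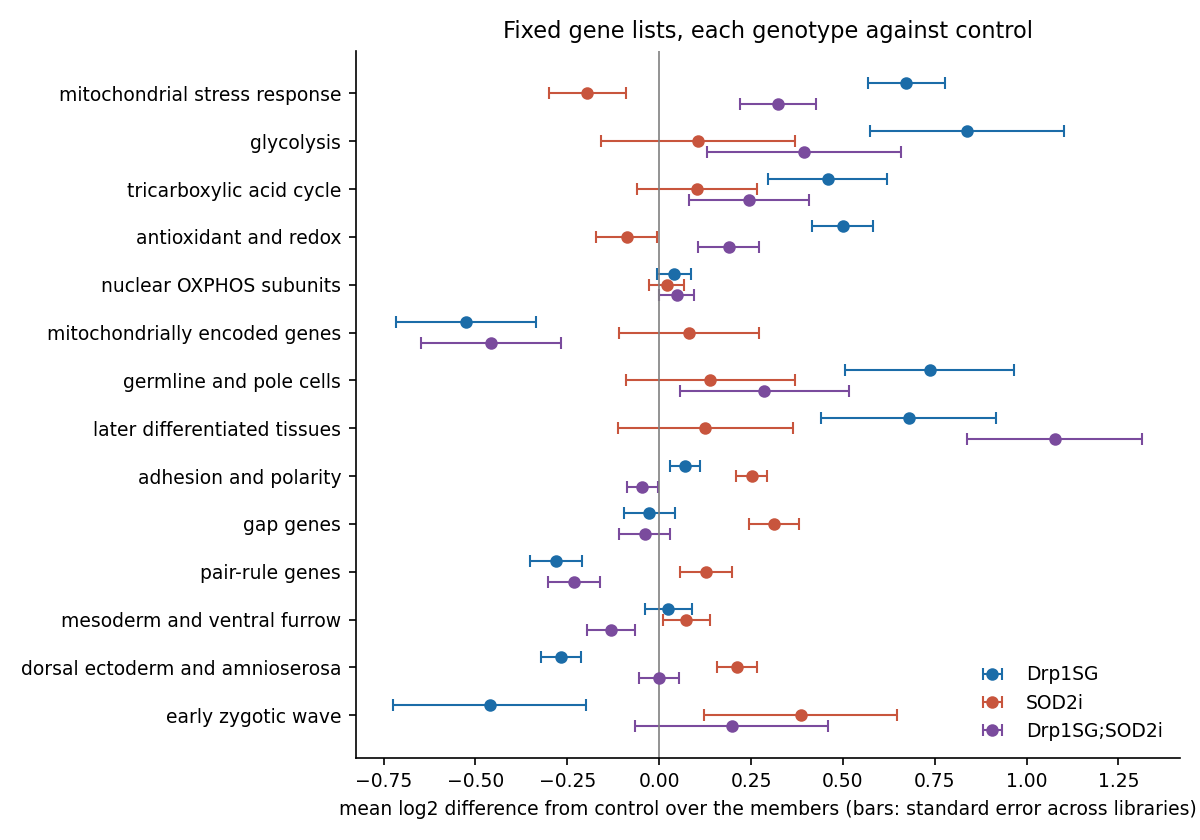
Mean log2 difference from control (± standard error) of 14 gene lists in Drp1SG, SOD2i and the double genotype. The mitochondrial stress response stands at 0.67 in Drp1SG, -0.20 in SOD2i and 0.32 in the double genotype.

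In the double genotype against control, Arc1 rose to 12.8 ± 0.313 CPM (log2 fold change 4.41 ± 0.19, adjusted p = 1.89e-07). Dmel_CG8799 rose by 4.00, pst by 3.52, daw by 2.69, DNaseII by 2.59, Pde8 by 2.54 and side by 2.32. Drep1 rose by 2.06, the zinc finger gene klu by 1.93 and jtb by 1.83. TkR86C fell by 3.84, to 1.70 ± 0.518 CPM, close to its level in both single genotypes. BobA fell from 153 ± 28.9 to 36.5 ± 4.81 CPM (log2 fold change -2.07 ± 0.15, adjusted p = 7.56e-06). Mur2B fell by 1.55, Con by 1.51, Kul by 1.28, sturkopf by 1.19, the cell recognition molecule Dscam2 by 1.17 and the juvenile hormone esterase Jhe by 1.10. srRNA of the mitochondrial genome also fell by 1.17 (adjusted p = 0.0376), a call lost without Control replicates 1 or 3 or any 1 library of the double genotype (adjusted p of up to 0.135). In total 879 genes were called, 456 higher and 423 lower, and 429 changed at least 2-fold. The majority turned with upper-quartile scaling (385 higher and 420 lower), a filter of 1 CPM (350 and 401), limma (428 and 458) and DESeq2 (643 and 676). The count was 494 and 543 without Control replicates 2 and 3, 503, 560 and 467 without the double genotype's replicates 1, 2 and 3, and 1319 by DESeq2.

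Later differentiated tissue markers were higher in the double genotype, 5 of 18 higher and 0 lower (8 higher adjusted over the list alone), by a mean log2 difference of 1.08 ± 0.24 (camera adjusted p = 0.00555, adjusted p = 0.623 with an estimated correlation). Markers of other cell types were not called as lists there but had higher means too, by 0.70 ± 0.17 for follicle cells (2 of 7 higher), 0.67 ± 0.21 for hemocytes (3 of 10 higher) and 0.47 ± 0.13 for immune effectors (0 of 8 called), with camera adjusted p of 0.22, 0.294 and 0.22. The follicle cell and immune effector means lay below 0 log2 CPM in every library, with 7 of 25 and 8 of 28 members tested, so these are trace levels. In Drp1SG the later tissue list differed by 0.68 ± 0.24, with 6 higher and 1 lower, and was not called (camera adjusted p = 0.213). btl, the FGF receptor of the trachea, rose from 14.1 to 34.0 CPM and brp, an active zone protein of synapses, from 1.52 to 3.46 CPM. The muscle genes wupA and Mhc rose by 3.26 and 2.54, and by 2.33 and 1.92 without the double genotype's replicate 2, and the Mhc call was lost without Control replicate 2 (adjusted p = 0.0507). Of 17 mesoderm genes, mthl1, stumps and T48 were lower (9 lower adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.623 with an estimated correlation). mthl1 fell from 108 to 80.6 CPM, and the FGF pathway adaptor stumps from 283 to 205 CPM, a call lost without the double genotype's replicates 1 or 3 (adjusted p of up to 0.0636). The T48 call was lost without Control replicates 2 or 3 or any 1 library of the double genotype (adjusted p of up to 0.0908). The pair-rule list was lower (camera adjusted p = 0.00555, adjusted p = 0.623 with an estimated correlation), and so were mitochondrially encoded transcripts, by -0.46 ± 0.19 (camera adjusted p = 0.00431, adjusted p = 0.713 with an estimated correlation). The maternal list was called higher with 0 genes called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.00555, adjusted p = 0.713 with an estimated correlation). That list call was lost without Control replicate 3 (adjusted p = 0.182) or the double genotype's replicate 1 (adjusted p = 0.116). Nuclear genes for oxidative phosphorylation were called higher once the maternal index was a covariate (camera adjusted p = 0.294 without it and 0.0194 with it). In the mitochondrial stress response, crc rose from 155 to 253 CPM and Xrp1 from 8.94 to 19.8 CPM, and the list was not called (camera adjusted p = 0.122).

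The double genotype against Drp1SG asks which transcripts differ with SOD2i when Drp1SG is present. kek1 rose from 1.22 ± 0.454 to 88.5 ± 16.2 CPM (log2 fold change 6.17 ± 0.32, adjusted p = 4.74e-07) and Sema2b from 4.65 ± 0.478 to 69.2 ± 5.93 CPM (log2 fold change 3.89 ± 0.15, adjusted p = 8.49e-08). DNaseII rose by 2.57, para by 2.13, Pde8 by 2.04, NK7.1 by 1.48, klg by 1.45, GstE11 by 1.42, Dmel_CG8799 by 1.36 and miple1 by 1.28. Besides Sod2, dhd fell by 2.23, Drep1 by 1.92, Fas3 by 1.79, Mis12 by 1.75, Tpi by 1.70 and daw by 1.65. The mitochondrial stress response fell relative to Drp1SG, with Shmt at 6.13 against 12.7 CPM and Roe1 lower by a log2 fold change of -0.57 (4 of 15 lower, 5 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.255 with an estimated correlation). With the maternal index as a covariate its mean difference went from -0.35 ± 0.10 to -0.20 ± 0.05 and it was not called (camera adjusted p = 0.0633). The early zygotic wave rose, with tld at 116 against 75.2 CPM and Z600 at 169 against 97.1 CPM (2 of 9 higher, 7 adjusted over the list alone, camera adjusted p = 6.12e-04, adjusted p = 0.819 with an estimated correlation). Of the 32 maternal transcripts, 7 were lower (9 adjusted over the list alone, camera adjusted p = 8.56e-04, adjusted p = 0.848 with an estimated correlation), with Hsp83 at 513 against 867 CPM. In total 1072 genes were called, 498 higher and 574 lower. The majority turned with upper-quartile scaling (485 higher and 447 lower), with the maternal index as a covariate (1263 and 1200) and without the double genotype's replicate 1 (50.5% higher). The count was 657, 587 and 635 without Drp1SG replicates 1, 2 and 3, 675, 571 and 703 without the double genotype's, 1848 in a fit of only these libraries and 2463 with the maternal index as a covariate.

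The double genotype against SOD2i asks which transcripts differ with Drp1SG when SOD2i is present. mthl8 stood at 23.4 ± 2.23 CPM in the double genotype, at least 499-fold above SOD2i and close to control. daw rose by 3.16, para by 2.21, nAChRalpha5 by 1.55, ct by 1.54, Sgsh by 1.49, Sep4 by 1.47, Xrp1 by 1.41, cib by 1.39 and Uch by 1.38. tbc fell by 2.19, kek1 by 1.97, Arc1 by 1.85, Ugt36E1 by 1.80, vir-1 by 1.56, Drep1 by 1.51, Fas3 by 1.32 and Mis12 by 1.23. Sod3 fell from 162 ± 3.37 to 52.6 ± 5.82 CPM (log2 fold change -1.62 ± 0.10, adjusted p = 2.08e-06), near its control level of 44.0 CPM. In total 1903 genes were called, 1036 higher and 867 lower, and 1059 higher and 566 lower with upper-quartile scaling. The count was 1199 without SOD2i replicate 3, and 1230 and 1248 without the double genotype's replicates 1 and 3.

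Adhesion and polarity genes were lower in the double genotype than in SOD2i, 11 of 22 lower and 0 higher (13 lower adjusted over the list alone, camera adjusted p = 2.12e-06, adjusted p = 0.321 with an estimated correlation). baz went from 358 to 245 CPM, sdt from 691 to 446 CPM and pyd from 1517 to 1154 CPM. Of 10 gap genes, 7 were lower (camera adjusted p = 1.46e-04, adjusted p = 0.321 with an estimated correlation), among them hkb, 61.0 to 38.4 CPM. Of 10 pair-rule genes, 6 were lower (camera adjusted p = 0.00172, adjusted p = 0.334 with an estimated correlation), among them opa, 516 to 330 CPM, and h, 194 to 126 CPM. Of 17 mesoderm genes, 7 were lower (camera adjusted p = 0.0045, adjusted p = 0.363 with an estimated correlation), among them mthl1, 139 to 80.6 CPM, and Mdr49, 522 to 299 CPM. The mitochondrial stress response was higher, 7 of 15 higher and 0 lower (camera adjusted p = 0.00323, adjusted p = 0.290 with an estimated correlation). ImpL2 went from 41.5 to 82.9 CPM, crc from 165 to 253 CPM and Hsc70-5 from 73.0 to 98.7 CPM. Of 15 mitochondrially encoded genes, 5 were lower (camera adjusted p = 8.80e-05, adjusted p = 0.398 with an estimated correlation), with ND4L at 20.3 against 32.4 CPM. Adjusted over the list alone, the counts were 7 lower for gap genes, 7 lower for pair-rule genes, 9 lower for the mesoderm list, 8 higher for the mitochondrial stress response and 8 lower for mitochondrially encoded genes.

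The interaction, the log2 change of the double genotype beyond the sum of both single changes, was called for 1631 genes, 907 above the sum and 724 below it. With upper-quartile scaling these were 1013 and 465, and the maternal index as a covariate gave 2645 genes in all. Arc1 lay 5.58 ± 0.25 log2 units below the sum (interaction -5.58, adjusted p = 8.47e-08), and Drep1 had an interaction of -5.49 ± 0.23 (adjusted p = 8.47e-08). For Sod3 it was -3.19 ± 0.14, with 44.0, 130, 162 and 52.6 CPM in control, Drp1SG, SOD2i and the double genotype. TkR86C, near 1.7 CPM in each altered genotype, had an interaction of 3.87 ± 0.25 (adjusted p = 1.37e-06), since the 2 single falls did not add up. Sod2 itself had an interaction of 0.78 ± 0.23 (adjusted p = 0.0414), a call lost without any 1 of 10 libraries, all but SOD2i replicate 2 and the double genotype's replicate 1 (adjusted p of up to 0.0927).

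The share of each single genotype's change that was kept in the double genotype was measured on genes chosen without the replicate being measured. Of the Drp1SG change, 0.486, 0.412 and 0.50 was kept for the 3 held-out replicates, and of the SOD2i change 0.373, 0.438 and 0.422. Among the SOD2i genes, those called higher kept 0.497 to 0.573 and those called lower 0.290 to 0.349. For comparison, 0.846 of the Sod2 log2 fold change and 0.227 of the Drp1 log2 fold change was kept. The Drp1 share is taken against control, and Drp1 stood at 61.3% of control in SOD2i and 121% in the double genotype. It therefore understates the Drp1 gain from SOD2i to the double genotype. Single and double changes were taken over the same control library, so a difference of control from every altered genotype counts as kept. The covariance of Drp1SG log2 fold changes was 0.454 with SOD2i, which lacks Drp1SG, and 0.404 with the double genotype (0.0701 and 0.0837 above 5 CPM). The shares therefore do not measure how much of a genotype's own effect was kept.

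**Figure D5:**
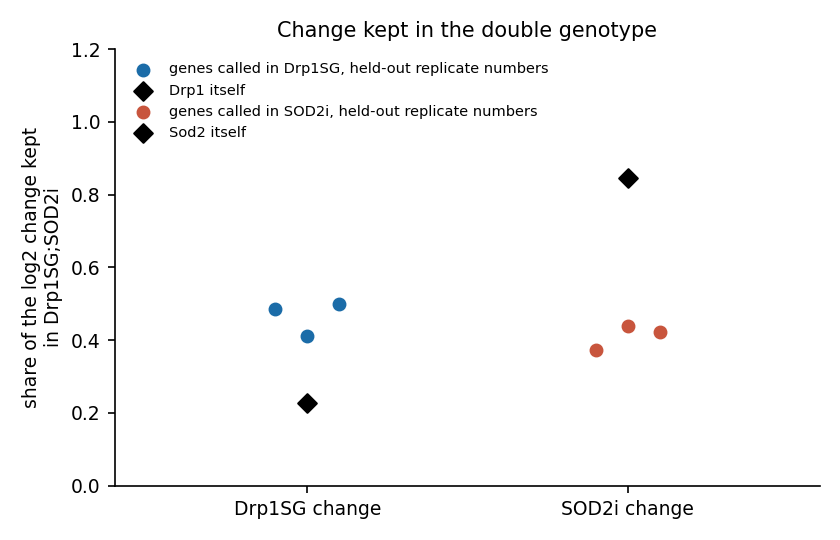
Share of the single genotypes' log2 change kept in the double genotype, 1 point per held-out replicate, beside the shares kept by Sod2 and Drp1. The held-out shares lie between 0.373 and 0.50, below the 0.846 of Sod2. They also count differences of control from every altered genotype. The share of Drp1, 0.227, is taken against control, and Drp1 stood at 61.3% of control in SOD2i.

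Changes against control were shared between genotypes. Drp1SG and SOD2i had 321 genes higher in both and 397 lower in both, against 99.1 and 112 for independent calls, and 83 called in opposite directions. Drp1SG and the double genotype shared 238 higher and 228 lower (44.3 and 37.4 for independent calls), and SOD2i and the double genotype 247 and 283 (47.1 and 54.3). All 3 comparisons use the same control libraries, which by itself links them. In 20 simulations of unchanged groups with shared controls, the correlation of log2 fold changes across genes was 0.506 for Drp1SG and SOD2i against 0.543 observed, and the covariance 0.0527 against 0.454. Over the 6252 genes above 5 CPM, the observed correlation of this pair was lower than in the simulations, 0.370 against 0.496, and the covariance higher, 0.0701 against 0.0166. For the other pairs over these genes the observed correlation was the higher, 0.601 against 0.497 for Drp1SG and the double genotype and 0.608 against 0.501 for SOD2i and the double genotype. The simulated correlation is set by the equal group sizes, and changes particular to a genotype can move the observed one either way. A correlation above or below the simulated one therefore does not decide whether changes were shared. Genes are not independent replicates, and the controls were not split, since a part would hold fewer than 2 libraries. At least 2-fold and in the same direction in all 3 genotypes changed 128 genes, 61 higher and 67 lower, among them Arc1, Dmel_CG8799, pst and Drep1 higher and TkR86C and Kul lower.

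The authors' deposited tables of DESeq2 results were set beside these values. In the authors' deposited tables, log2 fold changes correlated with those given here at r = 0.999 for Drp1SG across genes, 0.998 for SOD2i and 0.999 for the double genotype. At the authors' deposited adjusted p under 0.05, 2062, 1708 and 1117 genes differed from control, and of the genes called here 1679, 1646 and 806 were among them.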

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

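The results in this part were chosen by the interaction test. It asks whether the log2 change of the double genotype differs from the sum of both single changes. The tests of neighbouring genes, of younger embryos and of undeveloped eggs were chosen after the results they weigh were seen. The interaction was called for 1631 genes. Of 100 splits of the 12 libraries, 1 gave as many, the real one, and the highest other gave 57. The other splits mix genotypes, so differences between genotypes widen the spread within their groups and lower their counts. They cannot tell an interaction from other differences between genotypes, so they do not exclude chance for this count. Genes called with an interaction of at least 2-fold held 181 neighbouring pairs. Draws matched on expression gave a mean of 96.9 and a highest of 129 in 10000 (permutation p = 1e-04). Stretches of chromosome that differ between lines could therefore give part of the interaction calls, as could clusters of related genes regulated together. A collection window that differs between genotypes could do so too, and none of these was told apart by a test. For Sod2 the interaction was 0.78, with the limits on that call given above. mthl8 was at least 511-fold above the sum of the single changes. Other genes above the sum were para (4.05), TkR86C (3.87), Kul (3.40), kek1 (3.33), cib (2.44), nAChRalpha5 (2.33), Rpt3R (2.27), Sema2b (2.25) and miple1 (2.09). Genes below the sum were Arc1 (-5.58), DIP-beta (-5.57), Drep1 (-5.49), tbc (-4.53), Ugt36E1 (-3.93), Fas3 (-3.61), pst (-3.60), vir-1 (-3.37), Sod3 (-3.19) and Dmel_CG8799 (-3.11). Of these, Arc1, Drep1, Ugt36E1, pst, vir-1 and Dmel_CG8799 were at least 2-fold higher than control in all 3 genotypes, and TkR86C and Kul were lower in all 3. A change shared by all 3 genotypes enters the sum from both single changes, so by arithmetic alone it gives an interaction of opposite sign. The DIP-beta call was lost without any 1 library of control, Drp1SG or the double genotype (adjusted p of up to 0.0799), and its value was -1.77 without SOD2i replicate 3. Under the maternal index as a covariate it was -4.83 and not called (adjusted p = 0.0871).

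Gene lists below the sum were adhesion and polarity (camera adjusted p = 0.0037), maternal transcripts (0.00118), germline (0.0128), gap genes (0.0373), actomyosin regulators (0.0478) and glycolysis (0.0478), each with an adjusted p of 0.732 with an estimated correlation. In the adhesion list 6 of 22 genes were below the sum and 0 above (8 below adjusted over the list alone). baz had an interaction of -1.02, with 235, 325, 358 and 245 CPM in control, Drp1SG, SOD2i and the double genotype, and aPKC one of -0.38. The germline call was lost without Control replicate 3 (adjusted p = 0.0606) or SOD2i replicate 1 (0.0656), and the gap gene call without Control replicate 3 (0.0606) or the double genotype's replicate 3 (0.0721). The actomyosin call was lost without Control replicates 2 or 3, Drp1SG replicate 3, SOD2i replicate 3 or the double genotype's replicate 2 (up to 0.0758). The glycolysis call was lost without Control replicate 3, Drp1SG replicates 2 or 3, SOD2i replicates 1 or 3 or the double genotype's replicates 2 or 3 (up to 0.188). With the maternal index as a covariate, calls ended for glycolysis, whose mean went from -0.55 ± 0.37 to -0.03 ± 0.12 (camera adjusted p = 0.977), germline genes, from -0.59 ± 0.33 to -0.13 ± 0.08 (0.473), and actomyosin regulators, from -0.12 ± 0.08 to -0.02 ± 0.05 (0.0837). Calls were gained below the sum for the mesoderm list, from -0.23 ± 0.09 (camera adjusted p = 0.0784) to -0.31 ± 0.08 (0.00637), and for cytosolic ribosomal proteins, from 0.05 ± 0.11 (0.949) to -0.09 ± 0.06 (5.49e-04). Of 100 splits, 59 called as many lists as the real 6, with up to 20 in another split, so chance cannot be excluded for the number of lists.

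For the comparisons of 2 genotypes, 10 splits of 6 libraries are too few for a share under 0.05. Genes called in the real split and in the highest other were 1830 and 0 for Drp1SG, 2286 and 544 for SOD2i, 879 and 0 for the double genotype, 1072 and 0 against Drp1SG, and 1903 and 0 against SOD2i, with 1 split in 10, the real one, as large. For lists the real and highest other counts were 9 and 17 for Drp1SG (5 of 10 splits as large), 2 and 13 for SOD2i (10 of 10) and 5 and 15 for the double genotype (10 of 10). Against Drp1SG they were 5 and 13 (9 of 10), and against SOD2i 11 and 15 (2 of 10). The other splits mix genotypes, which widens the spread within their groups, so low gene counts are to be expected there. Splits that call more lists than the real one may come from correlation among the genes of a list, which the preset value ignores. They may also come from differences between libraries, those of genotype included, since each other split mixes the genotypes unequally. These were not told apart by a test.

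The first pattern weighed is the 128 genes that changed at least 2-fold in the same direction in all 3 genotypes, 61 higher and 67 lower, of 1401 changed 2-fold in any. Of these, 21 had a mean of at least 5 CPM, among them Arc1, TkR86C and Dmel_CG8799. Simulated unchanged groups compared with shared controls gave at most 0 such genes in 20 simulations. Thresholds on adjusted p and fold make 0 the expected outcome there, so this decides nothing, and overlap raised by the shared control libraries stays open. Leaving out a control library left 141, 108 and 96 such genes, of which 104, 91 and 90 were among the 128, which argues against 1 control library that stands apart. The set held 15 pairs of neighbouring genes, against a mean of 2.83 and a highest of 10 in 10000 draws from the genes changed 2-fold in any genotype (permutation p = 1e-04, the smallest they can give). Stretches of chromosome that differ between lines could therefore explain part of the set. Neighbouring pairs were also in excess among genes changed 2-fold between the double genotype and Drp1SG (56, against a mean of 20.1 in draws matched on expression) or SOD2i (130 against 59.3), so the excess does not single out the control strain. Clusters of related genes regulated together would also give neighbouring pairs. A shared response to altered mitochondria stays open as well, untested, since the labels do not describe the parental lines.

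The second pattern is the smaller change in the double genotype, with 879 genes called against 1830 and 2286 in the single genotypes. On held-out replicates at most 0.438 of the SOD2i change was kept over all genes called without them. At most 0.453 was kept over those that also changed 2-fold and 0.639 over the higher ones of these. Of the Sod2 log2 fold change, 0.846 was kept. This argues against a weaker lowering of Sod2 as the whole cause only if other genes change in proportion to the log2 Sod2 level. That proportion was not tested. All shares of change given here also count differences of control from every altered genotype. A weaker Drp1SG could explain the loss of the Drp1SG change, since at most 0.50 of that change was kept on held-out replicates over all genes called without them (0.513 over those that also changed 2-fold, and 0.537 over genes chosen on all libraries). The Drp1 gain over the matched genotype was also lower in every library of the double genotype (up to 22.1 CPM) than in any Drp1SG library (from 35.0 CPM). On the log2 scale, where the lower Drp1 level of SOD2i is taken into account, no difference between the gains was called (interaction -0.24, adjusted p = 0.467). This stays open, as Drp1 reads cannot be divided here into transgene and endogenous gene. An antagonism between the alterations, a diluted driver and a different line background stay open too.

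The third pattern is the rise in Drp1SG of lists that also follow the maternal index. With the index as a covariate, the mean difference fell from 0.84 ± 0.26 to 0.13 ± 0.11 for glycolysis and from 0.46 ± 0.16 to 0.01 ± 0.05 (0.0146) for the citrate cycle. Both calls ended because the difference shrank, so maternal transcript content may account for them. The mitochondrial stress response fell from 0.67 ± 0.10 to 0.40 ± 0.06 and was still called (camera adjusted p = 0.0109). The index did not overlap between control (4.81 to 5.69) and Drp1SG (6.14 to 6.52), so the adjusted difference rests on extending a slope. An index that measures maternal content imperfectly can also leave part of a difference. The remainder therefore does not decide whether maternal content is the whole cause of this rise. Younger embryos would be expected to raise the early zygotic wave, whose median log2 fold change was -0.61. They stay open, since its call was lost without Control replicate 1 (camera adjusted p = 0.0641) and its relation to the maternal index within genotypes rests on 2 libraries. Undeveloped eggs would lower zygotic lists alike, and the mesoderm median was -0.055. That comparison needs the same early zygotic fall, so undeveloped eggs are not excluded by it, although per the labels embryos were sorted by hand to leave out those not developing. Slower clearance of maternal transcripts in Drp1SG stays open, and so does a different collection window.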

How the results depend on the processing

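The alternatives on maternal transcripts and the tests of overlap were chosen after the data were seen. With a 2-fold threshold added, counts fell to 742, 885 and 429 for Drp1SG, SOD2i and the double genotype against control, 421 and 705 for the double genotype against Drp1SG and SOD2i, and 942 for the interaction, since fewer genes meet both conditions. A fit of only the groups compared gave 1263 for SOD2i against control and 1848 for the double genotype against Drp1SG. For Drp1SG against control such a fit gave 1681, so which single genotype had more calls depended on the fit. DESeq2 gave 1319 for the double genotype against control. The maternal index as a covariate gave 2463 for the double genotype against Drp1SG and 2645 for the interaction, and leaving out Control replicate 3 and SOD2i replicate 2 gave 1624 for the double genotype against Drp1SG. Replicate spread was unequal, and the main fit pools it over all genotypes. Over genes above 5 CPM, the median SD of log2 CPM was 0.143 in control, 0.083 in Drp1SG, 0.139 in SOD2i and 0.085 in the double genotype. Apart from the 2-fold threshold, the cause of these moved counts was not tested. The other counts of genes stayed within 1.5 times under both scalings, both filters, limma and the replicate block.

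Among libraries left out singly, gene counts ranged from 1112 to 1644 for Drp1SG, 467 to 999 for the double genotype, 571 to 703 for the double genotype against Drp1SG and 1199 to 2112 against SOD2i. The libraries that moved them beyond 1.5 times are named in the report, and fewer samples per genotype are part of the cause. Lists called ranged from 2 to 4 for SOD2i (4 without Control replicate 1 or SOD2i replicate 2), 4 to 11 for the double genotype (9, 11 and 8 without Control replicates 1 and 2 and its replicate 3) and 2 to 7 for the interaction (2 without Control replicate 3).

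With an estimated correlation in camera, 0 lists were called in each comparison (0 for Drp1SG, 0 for SOD2i, 0 for the double genotype, 0 and 0 for it against Drp1SG and SOD2i, 0 for the interaction), as each list's own correlation then replaces 0.01. fry called 5 lists for SOD2i and 2 for the interaction. The maternal index as a covariate, with the maternal list itself not tested, gave 4 lists for Drp1SG, of which the mitochondrial stress response and early zygotic wave were among the 9 called without it, and nuclear oxidative phosphorylation and cytosolic ribosomal protein genes were gained. It gave 3 for the double genotype against Drp1SG, of which the early zygotic wave was among the 5 and the mesoderm and cytosolic ribosomal protein lists were gained. Leaving out Control replicate 3 and SOD2i replicate 2 gave 4 for SOD2i. Of the 38 list calls, 26 held with fry, 27 in every fit without 1 library, and 37 each with DESeq2 size factors and with replicate number as a block.

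Same-numbered replicates did not pair (mean r = -0.012 over 18 pairs). With replicate number as a block, the Sod2 interaction was 0.783 and no longer called, and without the double genotype's replicate 2, the library with the highest adjusted p when left out, it was 0.653 and not called. The other Sod2 and Drp1 results kept their call under DESeq2 size factors, the block, DESeq2 and each left-out library, and those called kept their direction.

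The correlation of log2 fold changes across genes ranged without single libraries from 0.465 (SOD2i replicate 1) to 0.597 (Control replicate 1) for Drp1SG and SOD2i, from 0.541 (Drp1SG replicate 1) to 0.661 (Control replicate 1) for Drp1SG and the double genotype, and from 0.453 (SOD2i replicate 1) to 0.580 (Control replicate 1) for SOD2i and the double genotype.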

Other observations

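Single genes changed in several lists that were not called in the same comparison. In the Notch response list, 7 of 20 genes were lower in Drp1SG and 0 higher (7 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.0972). Brd fell from 223 to 132 CPM and BobA from 153 to 91.4 CPM. Of 18 markers of later tissues, 6 were higher and 1 lower in Drp1SG (mean log2 difference 0.68 ± 0.24, camera adjusted p = 0.213), and 3 higher and 2 lower in SOD2i (0.13 ± 0.24, camera adjusted p = 0.852). Against the direction of most in Drp1SG, Tm1, a tropomyosin, stood at 850 CPM in control, 481 in Drp1SG, 519 in SOD2i and 840 in the double genotype. Among hemocyte markers, Hml rose from 1.68 CPM to 4.63 in SOD2i and 6.69 in the double genotype, whereas Pxn fell from 4.88 to 1.75 CPM in SOD2i. Hemocytes were not called as a list against control, with a lowest camera adjusted p of 0.213 over the 3 genotypes and 4 of 10 genes higher in Drp1SG. Of 16 segment polarity and Hox genes, 2 were higher and 3 lower in Drp1SG, 1 higher and 0 lower in SOD2i and 0 higher and 1 lower in the double genotype. Among them en fell from 67.3 to 44.2 CPM in Drp1SG and ptc rose from 682 to 896 CPM in SOD2i (lowest camera adjusted p = 0.0955).

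Heat shock genes were higher in the double genotype than in SOD2i, 4 of 16 higher and 0 lower (5 higher adjusted over the list alone, camera adjusted p = 0.0045, adjusted p = 0.334 with an estimated correlation). Hsp68 went from 3.25 to 6.75 CPM and Hsp23 from 32 to 47.9 CPM. Lower than in SOD2i were the dorsal ectoderm list (5 of 16 genes lower and 0 higher, 6 lower adjusted over the list alone, camera adjusted p = 0.00921, adjusted p = 0.398 with an estimated correlation), with tld at 116 against 161 CPM, and the early zygotic wave (2 of 9 lower, 3 adjusted over the list alone, camera adjusted p = 0.0391, adjusted p = 0.548 with an estimated correlation). The early zygotic call was lost without SOD2i replicate 3 (0.151) or the double genotype's replicate 3 (0.0691). Of 18 cellularization genes, RhoGAP71E, 458 to 368 CPM, and pnut were lower (also 2 adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.328 with an estimated correlation), a list call lost without SOD2i replicate 3 (0.0560) or the double genotype's replicate 2 (0.0761). The pnut call was lost without SOD2i replicates 2 or 3 or the double genotype's replicates 1 or 3 (adjusted p of up to 0.0720). Of 7 follicle cell genes 3 were higher, at 1.10 CPM or less (4 adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.321 with an estimated correlation), a list call lost without SOD2i replicates 1 or 3 (0.0747 and 0.0560) or the double genotype's replicates 2 or 3 (0.0516 and 0.0513), or with the maternal index as a covariate (0.0514).

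Against Drp1SG, the germline list was lower in the double genotype (3 of 17, 4 adjusted over the list alone, camera adjusted p = 0.00551, adjusted p = 0.819 with an estimated correlation), by a mean of -0.45 ± 0.23, and by -0.10 ± 0.06 and no longer called with the maternal index as a covariate (camera adjusted p = 0.514). The dorsal ectoderm list was higher (2 of 16 genes, also 2 adjusted over the list alone, camera adjusted p = 0.0370, adjusted p = 0.819 with an estimated correlation), a call lost without Drp1SG replicates 2 or 3 (0.110 and 0.120), the double genotype's replicate 3 (0.109), or with the covariate (0.514, mean difference 0.27 ± 0.05 before and 0.21 ± 0.05 after).

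The remaining lists were not called against control in any genotype without a covariate. Their lowest camera adjusted p over the 3 genotypes was 0.118 for cell death and DNA damage, 0.213 for JNK and stress signalling and for mitochondrial ribosomal proteins, 0.22 for mitochondrial dynamics, follicle cell and immune effector genes, and 0.231 for heat shock. It was 0.270 for the proteasome, 0.341 for neuroectoderm, 0.348 for cellularization genes, 0.363 for histones, 0.429 for lipid metabolism, 0.467 for cell cycle regulators and 0.474 for cytosolic ribosomal proteins. Of 13 mitochondrial dynamics genes, edgeR called Drp1 higher in Drp1SG, Drp1 and Mul1 lower in SOD2i, and 1 gene lower in the double genotype. Adjusted over the list alone, 1 was higher and 3 lower in Drp1SG and likewise in SOD2i. With the maternal index as a covariate, 23 of 84 cytosolic ribosomal protein genes were higher in Drp1SG and 0 lower, and the list was called higher in Drp1SG (camera adjusted p = 1.09e-07) and in the double genotype (8.32e-05). Its mean difference went from -0.04 ± 0.08 to 0.15 ± 0.06 in Drp1SG and from -0.02 ± 0.08 to 0.06 ± 0.04 in the double genotype. The index did not overlap between control and Drp1SG, so the Drp1SG rise appears only by extending a slope. The covariate also gained a call of the dorsal ectoderm list higher in SOD2i (camera adjusted p = 0.178 before and 0.0498 after) and of actomyosin regulators lower in the double genotype than in SOD2i (0.0527 and 0.0333).

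Within genotypes, the lipid metabolism list mean rose with the maternal index (r = 0.99) and cytosolic ribosomal proteins fell (r = -0.88), over 12 libraries taken as deviations from their genotype mean. The permutation p was 0.0019 and 0.001, and 0.0209 and 0.0165 after adjustment over 33 lists. Spearman's rho was 0.97 and -0.96. Without the 2 libraries whose index deviation lay farthest from the median, r was 0.98 and -0.81, with both still entering the genotype means. Of the germline and cell cycle lists, 7 and 4 genes are in the maternal list itself. Their other 10 and 17 genes gave r = 0.95 and 0.95 and rho = 0.96 and 0.96 (permutation p = 0.007 and 0.0019 for r, 0.033 and 0.0209 after adjustment), and r = 0.93 and 0.88 without those 2 libraries.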
